A study of Rattus norvegicus with 12 samples.

How the data were processed

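Total RNA of 12 samples of primary rat IMCD cells was measured on Affymetrix Rat Gene 1.0 ST arrays, 3 samples in each of 4 groups (24 h or 48 h at 300 or 640 mOsm/kg, after 4 days at 640). Per the labels' protocols, RNA was extracted with Trizol and used only where its integrity number was high. Groups and replicate numbers were taken from the sample titles. The short codes in the sample descriptions give other osmolalities for the 300 group at 24 h and the 640 group at 48 h, while the titles, the treatment labels and the design text give 300 and 640, which are used here.

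The authors deposited 1 table of log2 expression values per probe set and array. Per the submitters' processing notes the values come from RMA (background correction, normalization between arrays and summary of probes) run with Affymetrix Power Tools, with versions not given in the sources used here. The deposited log2 values are not centred per gene. Their array medians differ, from 5.80 to 6.42 over all 27596 probe sets, so the 12 arrays are not on one common scale, and whether they went through RMA together is not given in the sources used here. A scale that differs between times shifts all changes over time, and one that differs between arrays of one group enters the spread of the genes. Centring the arrays raised the number of calls, although the standard error of some genes was larger on centred arrays. No probe intensities or detection calls were used here, so a lower limit of detection is unknown. No date or batch of hybridisation was given in the sources used here, and each time and osmolality cannot be checked against such a batch.

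Probe sets were named through the gene table of the array platform. Of 27596 probe sets, 15310 had 1 gene symbol, 323 had several and were not named, and 11963 were not listed and stay unnamed. The Entrez identifiers of 15279 of the probe sets with 1 symbol matched the current RefSeq gene table, 31 did not, and 0 symbols had to be updated. For each gene the probe set with the highest mean over all arrays was used, which left 14506 genes, 527 of them with several probe sets. Of the called genes 0 of 13 at 24 h and 3 of 104 at 48 h had several, and 0 had a probe set of opposite sign. Slc6a12 was not among the named genes, and Hspa1b only shared a probe set with near-identical genes, so neither is analysed here.

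Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values, in a model with 1 mean per group over all 12 arrays (8 residual degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 14506 genes. Contrasts were 300 minus 640 at 24 h and at 48 h, their mean, their difference (48 h minus 24 h), and 48 h minus 24 h at each osmolality. Errors given with log2 changes are moderated standard errors, and those given with levels are standard deviations of 3 arrays. A total of 33 gene lists was tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 33 lists of a contrast, with the correlation estimated from the arrays and fry as alternatives. Array medians were compared with two-sided exact permutation tests.

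The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named 8 genes of osmolyte and water transport and heat shock, the 10 largest rises and falls among called genes at each time whose arrays at 300 and 640 did not overlap, up to 4 called members per list with the smallest adjusted p, and the 5 largest in each direction for the difference between times and for time at each osmolality. As 0 genes were called for the last 3 on the deposited values, the genes named for them come from centred arrays and were chosen after the values were seen, as were others where the text says so. Symbols of uncharacterised loci, olfactory and vomeronasal receptors and microRNAs were left out by the rule.

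Fixed before the data were examined were further fits with cyclic loess between arrays, centring each array on its median, leaving out the dimmest 30% of genes, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, every probe set, only the groups compared, the replicate number as a block and leaving out each array. Chosen after seeing the data were leaving out the pair of arrays with the lowest medians at 24 h, and estimated correlations on centred arrays. On simulated data with the spread of the real arrays and 200 changed genes of 14506, the 24 h test recovered 44% of log2 changes of 1 and 96% of changes of 2, with 4 false calls of 144, and the 48 h test recovered 42% and 91%, with 7 false calls of 140. With 1 list of 33 shifted by 0.50 in a simulated 24 h comparison, camera called that list and 0 others. In both simulations the noise was drawn independently for each gene and array. It lacked the scale differences and the inter-gene correlation of the real arrays, so the false calls counted there do not carry over to the real comparisons. No array pair held identical values, and the highest correlation between arrays was 0.995.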

Results

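The series measured messenger RNA in primary cultures of rat inner medullary collecting duct (IMCD) cells, the epithelium that lines the last part of the nephron and sets the final concentration of urine. Cells from kidneys of male Sprague-Dawley rats were grown for 4 days in medium of 640 mOsm/kg, an osmolality like that of the inner medulla, and then kept at 640 or moved to 300 mOsm/kg, close to that of plasma, for 24 or 48 h. Each of the 4 combinations of time and osmolality had 3 samples, each hybridised to 1 Affymetrix rat gene array, 12 arrays in all. The labels do not say whether the 3 samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The value table held 27596 probe sets as log2 intensities from 1.12 to 13.9, and 14506 genes were tested. The precision is limited by 3 arrays per group.

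The arrays did not share one scale. Over the genes tested, the median log2 value lay between 6.81 and 6.97 on the 6 arrays at 48 h. At 24 h it lay between 7.43 and 7.58 on 4 arrays, and it was 6.89 and 6.90 on replicate 1 at 300 and replicate 3 at 640. The mean of the array medians was 7.31 ± 0.371 at 300 and 7.30 ± 0.356 at 640 after 24 h (SD, n = 3), and 6.88 ± 0.0577 and 6.88 ± 0.0845 after 48 h. The means of the medians did not differ detectably between osmolalities (two-sided exact permutation p = 0.800 at 24 h and 1 at 48 h). With 3 arrays against 3 this p cannot go below 0.10. The means were 0.42 higher at 24 h than at 48 h (two-sided exact permutation p = 0.0238 over 924 splits of the 12 arrays). That test counts the 12 arrays as independent. Arrays of the same time resembled each other in sets across osmolalities (see Other observations). Its p therefore does not measure chance alone, and chance is not excluded for this difference of scale.

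The first comparison asks which transcripts differ between 300 and 640 mOsm/kg 24 h after the step down. Except in the comparisons over time, a rise or fall means a level higher or lower at 300 than at 640 at the same time. None of the 12 samples was taken before the step, so changes from the starting level are not measured. Aqp2, the vasopressin-regulated water channel of collecting duct principal cells, had a log2 level of 10.9 ± 0.737 at 640 and 7.31 ± 0.0913 at 300 (SD, n = 3), a 12.4-fold fall (log2 change -3.63 ± 0.318 SE, adjusted p = 0.000172). Ly6al, a member of the Ly6 family, fell 15.3-fold (log2 change -3.94 ± 0.521 SE, adjusted p = 0.00604). Mmp13, a collagenase, changed by -3.24, the protease inhibitor Serpina3n by -2.92 and the serine protease-like Prss35 by -2.78 on the log2 scale.

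In all, limma called 13 of 14506 genes at 24 h, 2 that rose and 11 that fell, each by at least 2-fold. The other falls were those of the lipoxygenase Alox15b (-2.17), the water channel Aqp1 (-1.98), the Ras-like Rasl10a (-1.84), Fxyd2, the gamma subunit of the sodium pump (-1.77), the mucin glycosyltransferase Gcnt3 (-1.73) and, named after its values were seen, the membrane mucin Muc1 (-1.62). The 2 rises were those of Slc16a6, of the monocarboxylate transporter family (log2 change 1.29 ± 0.224 SE, adjusted p = 0.0469), and Cyp1b1, a cytochrome P450 (1.26 ± 0.198, adjusted p = 0.0178). With each array centred on its own median, 95 genes were called, 40 that rose and 55 that fell, all 13 above among them, so that the share of rises moved from 15.4% to 42.1%. The count was 24 without replicate 1 at 300 (13 rises and 11 falls), and 8 without replicate 3 at 300 and 4 without replicate 1 at 640, with falls only. Without replicate 2 at 300 it was 12 and without replicate 3 at 640 it was 13, again with falls only. It was 20 without the pair of arrays with low medians (6 rises and 14 falls). In a fit of the arrays at 24 h alone it was 3, all falls. At 300 and 640 the 3 arrays did not overlap for 4.27% of genes. Chance gives 10% for exchangeable arrays, which these are not, since each group holds 1 array with a low median that makes the groups overlap. The share can therefore not be read against the 10%.

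Of 13 measured organic osmolyte genes, which let medullary cells take up or make the solutes that balance a hyperosmolar surrounding, 8 were lower at 300 at 24 h. Akr1b1, the aldose reductase that makes sorbitol, had a log2 change of -1.16 ± 0.205 SE that did not pass over all genes (adjusted p = 0.0521, and 0.0495 on arrays centred on their medians, where it passed). It stood at 13.0 ± 0.130 at 640 (SD, n = 3), near the top of the range of the arrays. Slc5a3, the myo-inositol cotransporter, had -1.94 ± 0.367 (adjusted p = 0.0770), the taurine transporter Slc6a6 -0.69 (adjusted p = 1.000) and Nfat5, the transcription factor of the hyperosmotic response, -0.21 (adjusted p = 1.000). Without replicate 1 at 300 or replicate 1 at 640 these values shrank to -0.45 or -0.46 for Slc6a6 and -0.12 or -0.11 for Nfat5. Arrays of the 2 osmolalities resembled each other in sets (see Other observations), and leaving out 1 array breaks such a set. These shifts therefore do not show that a change rests on 1 array. Of the 13 list members measured, 0 passed over all genes and 2 fell when adjusted over the list alone. The list as a whole was called downward (median -0.12, camera adjusted p = 0.00181), and had adjusted p = 0.668 with an estimated correlation.

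Among 22 principal cell and vasopressin response genes, 18 were lower at 300 at 24 h, 1 fell over all genes (Aqp2) and 3 fell when adjusted over the list alone. The vasopressin receptor Avpr2 had a log2 change of -1.18 (adjusted p = 0.178, and 0.0276 on centred arrays, where it passed), the basolateral water channel Aqp3 -1.0 (adjusted p = 0.702) and the urea transporter Slc14a2 -1.33 (adjusted p = 0.933). Without replicate 1 at 300 the value of Slc14a2 was -0.72. That array (7.44) was the lowest at 300, and replicate 3 at 640, which resembled it, was the lowest at 640 (8.97). Leaving out only 1 of the 2 therefore shifts the value. The list was called downward with a median of -0.29 (camera adjusted p = 5.75e-09, and adjusted p = 0.440 with an estimated correlation). Cell division genes were higher. All 24 mitosis genes were higher at 300, with a median of 0.75 (camera adjusted p = 2.66e-42, and adjusted p = 0.128 with an estimated correlation), and on the deposited values 0 passed over all genes and 17 rose when adjusted over the list alone. Over all genes on centred arrays 7 rose. Top2a, the topoisomerase of mitotic chromosomes, had 1.08 (adjusted p = 0.204, and 0.00990 on centred arrays) and cyclin Ccna2 1.27 (adjusted p = 0.204, and 0.00483 on centred arrays). Both passed there, and both were named after their values were seen. All 25 S phase genes were higher, with a median of 0.39 (camera adjusted p = 1.12e-16, and adjusted p = 0.440 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone.

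The extracellular matrix list (median 0.22), the actin and SRF or YAP target list (0.19), the Nrf2 target list (0.15) and the Atf4 target list (0.05) were called upward by camera at 24 h, with adjusted p = 0.440, 0.668, 0.668 and 0.868 in that order with an estimated correlation. On the deposited values none of their members passed over all genes or when adjusted over the list alone. The 26 interferon-stimulated genes were called upward too (median 0.23, adjusted p = 0.440 with an estimated correlation), with 0 members past the test over all genes and 5 when adjusted over the list alone. Usp18 had the smallest p (0.97, adjusted p = 0.242 over all genes and 0.0484 on centred arrays, named after its values were seen, as was Isg15 at 0.73). Downward calls were made for cholesterol synthesis, where all 19 genes were lower (median -0.19, adjusted p = 0.668 with an estimated correlation), and for prostaglandin synthesis and receptors (median -0.20, adjusted p = 0.5 with an estimated correlation), with 0 members past the test over all genes in either and 0 and 3 when adjusted over the list alone. Of markers of other cells, those of the thick ascending and thin limbs were called downward (median -0.07, adjusted p = 0.440 with an estimated correlation), with Aqp1 the 1 member that fell over all genes and 2 adjusted over the list alone. The endothelial markers were called downward as well (median -0.24, adjusted p = 0.668 with an estimated correlation), with 0 members past either test. In the called lists whose other counts changed on centred arrays, 2 principal cell genes fell, 1 member each of the osmolyte, cholesterol and prostaglandin lists fell, and 1 member each of the interferon, Nrf2 and Atf4 lists rose over all genes there. The other 20 lists were not called at 24 h. No list was called with an estimated correlation on the deposited values, and fry, which tests whether a list moves on balance one way, called 0 of 33. Its mixed test, for changes of either sign, called 3, those of osmolyte, principal cell and limb genes. The correlation estimated on the deposited values was 0.50 for principal cell and 0.60 for mitosis genes, against 0.016 and 0.20 on centred arrays. It thus also takes up the scale differences between arrays, and adjusted p resting on it, here and below, say little against a list. On centred arrays, 5 of the 13 lists were called with an estimated correlation, those of mitosis, principal cell genes, cholesterol synthesis, S phase and interferon-stimulated genes.

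**Figure D1:**
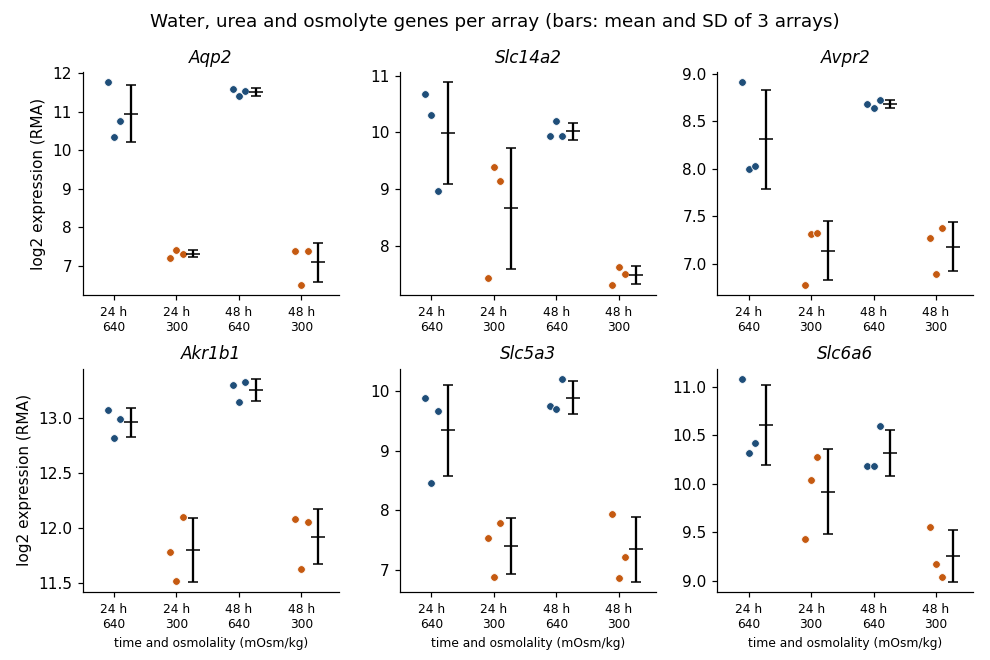
Log2 expression (RMA, vertical axis) of 6 genes of water, urea and osmolyte handling on each of the 12 arrays, by time and osmolality, with blue points at 640 and orange points at 300 mOsm/kg and black bars for the mean and SD of 3 arrays. The panel of Aqp2 shows means of 11.5 and 7.10 at 48 h, and the 24 h points of Slc14a2 spread over the widest range of that gene (SD 1.06 at 300).

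The second comparison asks the same 48 h after the step. Aqp2 was 21.3-fold lower at 300 (log2 level 11.5 ± 0.0922 at 640 and 7.10 ± 0.511 at 300, SD, n = 3, log2 change -4.41 ± 0.318 SE, adjusted p = 1.29e-05), and other genes of collecting duct water and urea transport fell with it. Aqp3 fell 4.56-fold (log2 change -2.19, adjusted p = 0.00203), Slc14a2 5.81-fold (-2.54, adjusted p = 0.0136) and Avpr2 2.83-fold (-1.50, adjusted p = 0.00954). These were 4 of 22 measured principal cell genes, and 8 fell when adjusted over the list alone, with the kinase Sgk1 at -0.88 (adjusted p = 0.0589 over all genes and 0.0104 on centred arrays, where it passed, named after its values were seen). The list had a median of -0.39 (camera adjusted p = 1.87e-13, and adjusted p = 0.379 with an estimated correlation).

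The osmolyte genes Slc5a3 and Akr1b1 fell 5.85-fold (log2 change -2.55 ± 0.367 SE, adjusted p = 0.00256) and 2.53-fold (-1.34 ± 0.205, adjusted p = 0.00390). Slc6a6 had -1.06 (adjusted p = 0.120, and 0.0202 on centred arrays, where it passed) and Nfat5 -0.22 (adjusted p = 1.000), which was -0.07 without replicate 2 at 300, -0.09 without replicate 3 at 640 and -0.33 without replicate 1 at 300. Of the 13 measured list members 2 fell over all genes and 3 when adjusted over the list alone (list median -0.22, camera adjusted p = 1.22e-06, and adjusted p = 0.439 with an estimated correlation). The chaperone genes Hspa2 and Hspa4l, of the families of 70 and 110 kDa heat shock proteins, fell by 1.36 and 1.37 on the log2 scale. They were 2 of 19 measured chaperones, and 3 fell when adjusted over the list alone. The list was called downward although its median was 0.02 and its mean -0.17 (camera adjusted p = 0.0418, and adjusted p = 0.702 with an estimated correlation), a call that centring the arrays ended (adjusted p = 0.0918).

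limma called 104 genes at 48 h, 25 that rose and 79 that fell, of which 23 rises and 78 falls were at least 2-fold. Besides those above, the largest falls were those of Ly6al (-5.74), the interferon-induced GTPase Mx1 (-4.03), Mmp13 (-3.54), Lypd2, of the Ly6 superfamily (-3.27), Slc4a11, of the bicarbonate transporter family (-3.09), Serpina3n (-3.03), Prss35 (-2.80), the chemokine Cxcl10 (-2.66) and Ly6i (-2.59). The largest rises were those of Capn6, a calpain without protease activity (log2 change 2.32 ± 0.258 SE, adjusted p = 0.000374), the keratins Krt16 (2.25) and Krt17 (1.87), which stressed and stratified epithelia make, the LIM protein Lmcd1 (2.09), Trh, the precursor of thyrotropin-releasing hormone (2.04), the prolactin family gene Prl8a9 (1.96), Lrrn1 (1.84), the metalloprotease Adamts1 (1.83), the muscle actin Acta1 (1.63) and the nucleosome-binding Hmgn2 (1.62). Chosen after their values were seen, the called genes Guca2a (guanylin, -1.91), Guca2b (uroguanylin, -1.16) and Gucy2g (a guanylate cyclase, -1.23) fell as well. Centring the arrays gave 269 calls, 76 rises and 193 falls, with all 104 among them. Leaving out any 1 of the 6 arrays of this time gave 66, 51 and 54 calls for replicates 1, 2 and 3 at 300 and 64, 63 and 55 for those at 640. The 3 arrays at 300 and at 640 did not overlap for 13.8% of genes, where chance gives 10% for exchangeable arrays. These arrays resembled each other in sets across osmolalities, so the 10% is no sure baseline.

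Among 26 measured interferon-stimulated genes, 3 fell over all genes at 48 h and 8 when adjusted over the list alone, against 1 that rose over the list alone. On centred arrays 8 fell and 1 rose over all genes. The 3 were Mx1 (16.3-fold, adjusted p = 4.65e-05), Ifit1 (log2 change -1.94, adjusted p = 0.00780) and Ifit3 (-1.58, adjusted p = 0.0182). The list was called downward (median -0.19, adjusted p = 0.512 with an estimated correlation). Prostaglandin genes were called downward with the lowest list median, -0.44 (camera adjusted p = 6.81e-07, and adjusted p = 0.379 with an estimated correlation). Of 15 measured 2 fell over all genes, the cyclooxygenase Ptgs1 (-1.29) and the prostaglandin exporter Abcc4 (-1.70), and 3 when adjusted over the list alone. Metabolic lists were called downward with 1 member each that fell over all genes. These were cholesterol synthesis (median -0.21, the sterol reductase Tm7sf2 -1.13), fatty acid and triglyceride synthesis (-0.22, malic enzyme Me1 -1.04) and glycolysis (-0.06, Pfkfb3 -1.68, a regulator of glycolytic flux). They had adjusted p = 0.608, 0.684 and 0.740 in that order with an estimated correlation, with 2, 1 and 1 members that fell when adjusted over the list alone. The cell volume and ion transport list (median -0.17, with Fxyd2 -2.30 the 1 member that fell over all genes) and the hypoxia list (-0.09, 0 members) were called downward, with adjusted p = 0.512 and 0.702 in that order with an estimated correlation, and 4 and 3 members fell when adjusted over the list alone.

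Upward calls at 48 h were made for mitosis, with all 24 genes higher (median 0.50), S phase (0.09), actin and SRF or YAP targets (0.28), extracellular matrix (0.29), p53 targets (0.19) and ribosome biogenesis (0.15). They had adjusted p = 0.439, 0.828, 0.439, 0.512, 0.684 and 0.702 in that order with an estimated correlation. The S phase call ended on centred arrays (adjusted p = 0.0555). Over all genes 1 matrix gene rose, periostin (Postn, 1.22), and 1 p53 target, Gadd45g (0.93), while 3 and 2 rose when adjusted over the list alone. On the deposited values 0 members of the other 4 lists rose over all genes or adjusted over the list alone. The troponin Tnnc1, outside these lists and chosen after its values were seen, rose (1.42). Markers of the thick ascending and thin limbs were called downward (median -0.18, adjusted p = 0.379 with an estimated correlation), with Aqp1 (-2.48) the 1 member that fell over all genes and 2 adjusted over the list alone. Endothelial markers were called downward (median -0.29, adjusted p = 0.608 with an estimated correlation), with 0 members past either test. The intercalated cell list was not called (median 0.03), and 1 of its 13 measured genes fell, the ammonia transporter Rhbg (-1.04). Lists of epithelial junctions and keratins (0.02), proximal tubule (0.00), fibroblast (0.19), macrophage (-0.22) and urothelium markers (0.12) were not called at either time. In the called lists whose other counts changed on centred arrays, the members that fell over all genes there were 5 of the principal cell list, 3 of the osmolyte list, 3 chaperones, 2 each of the cell volume, glycolysis, hypoxia and limb lists and 1 of the endothelial list. In such lists those that rose there were 2 each of the p53 and matrix lists and 1 each of the S phase and actin lists. No list was called on the deposited values with an estimated correlation and 0 of 33 by fry. The mixed test of fry called 7, those of osmolyte, chaperone, principal cell, cell volume, interferon-stimulated, prostaglandin and limb genes. On centred arrays 7 of the 18 were called with an estimated correlation, those of principal cell genes, cholesterol synthesis, mitosis, actin, prostaglandin, limb and endothelial genes.

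**Figure D2:**
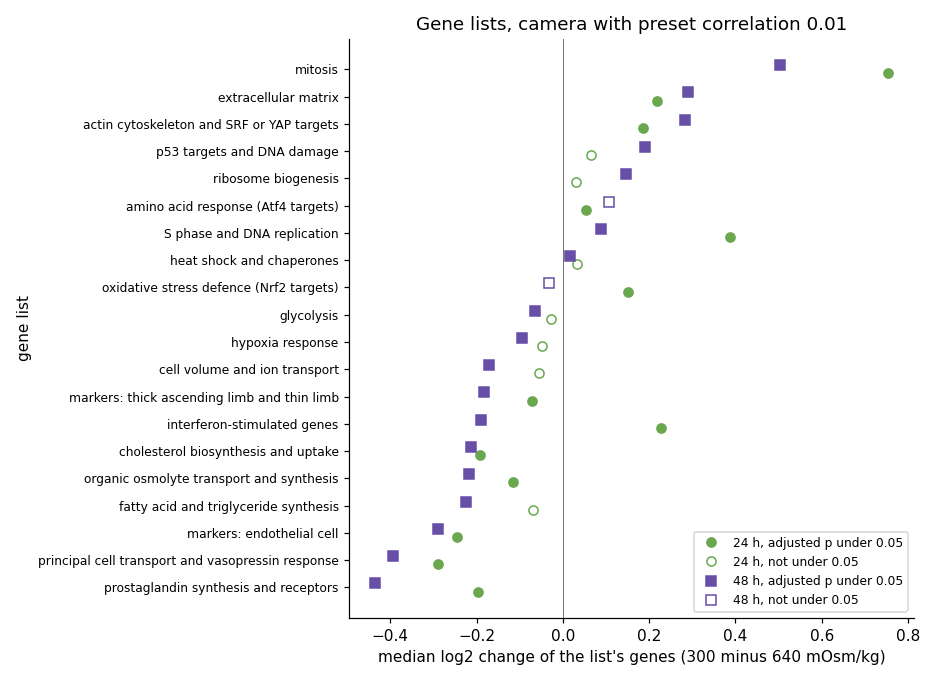
Median log2 change at 300 minus 640 mOsm/kg (horizontal axis) of the genes of the 20 lists that camera called at 24 h or 48 h with its preset correlation, with green circles for 24 h and purple squares for 48 h, filled where the adjusted p was under 0.05. The interferon-stimulated genes lie on opposite sides of 0, at 0.23 and -0.19, and the mitosis list lies at 0.75 and 0.50.

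The responses at the 2 times were then set against each other. Their log2 changes rest on different arrays, but the calls at both times use the same spread of each gene, estimated over all arrays. A gene with a small spread is thus favoured at both times. The counts given here for independent lists are therefore no sure baseline. All 11 genes that fell at 24 h also fell at 48 h, where 0.0599 would be shared by independent lists. Of the 2 that rose at 24 h, Slc16a6 and Cyp1b1, 0 passed at 48 h (log2 changes 0.70 and 0.75, adjusted p = 0.364 and 0.160). Both passed at 48 h on centred arrays (adjusted p = 0.0206 and 0.0196). On centred arrays 21 rises and 53 falls were shared, against 0.210 and 0.732 for independent lists. Across the 14506 genes, which are not independent replicates, the log2 changes at 24 h and 48 h had Pearson r = 0.713 and Spearman rho = 0.544, and 66.6% had the same sign. Of the 106 genes called at either time, 104 had the same sign at both. Averaged over both times, 185 genes were called, 59 that rose and 126 that fell, and on centred arrays 497, 193 that rose and 304 that fell. The count of 185 was 108 without replicate 1 at 640 and 24 h, 119 without replicate 2 and 110 without replicate 3 at 300 and 48 h. At 24 h, it was 260 without replicate 1 at 300 (137 rises and 123 falls) and 253 without replicate 3 at 640 (53 rises and 200 falls). Without both of these arrays, the pair with low medians at 24 h, it was 357 (136 rises and 221 falls). The balance of rises and falls thus shifted when 1 array of this pair was left out without the other.

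**Figure D3:**
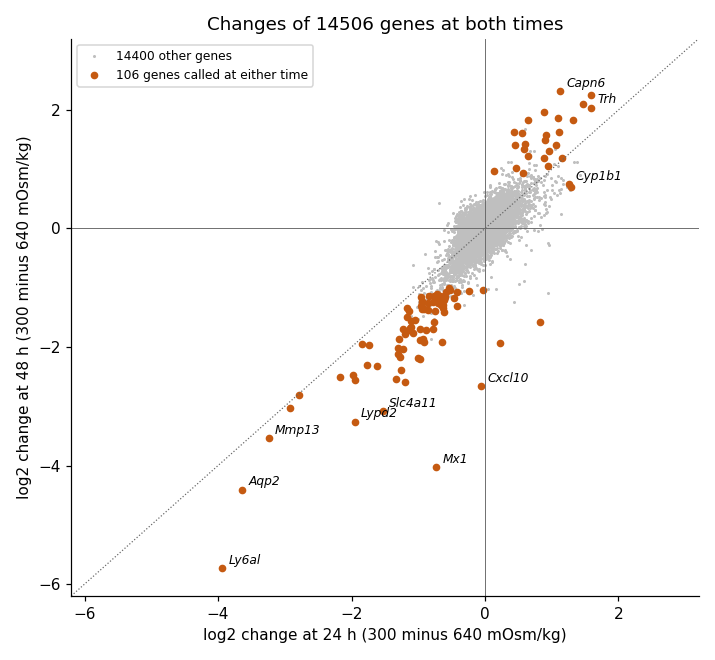
Log2 change at 300 minus 640 mOsm/kg of 14506 genes at 24 h (horizontal axis) and 48 h (vertical axis), with the 106 genes called at either time in orange, the other genes in grey and a dotted line of equal change. Aqp2 and Ly6al lie lowest at both times, and Mx1 and Cxcl10 have 24 h changes of -0.73 and -0.06 beside 48 h changes of -4.03 and -2.66. Without replicate 1 at 300 or replicate 1 at 640 the 24 h change of Mx1 was -0.40 or -0.31, and that of Cxcl10 ran from -0.41 to 0.24 with 1 array left out. Leaving out 1 array breaks a set of arrays that resembled each other across osmolalities.

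The test of the difference between the times asks which responses grew or shrank from 24 h to 48 h. The interferon-stimulated genes stood out: at 300 relative to 640, 23 of 26 were lower at 48 h than at 24 h, with a median difference of -0.36 (camera adjusted p = 9.25e-45, and adjusted p = 0.0773 with an estimated correlation). On centred arrays the list kept its call with an estimated correlation (adjusted p = 0.00211). Ifit3, for example, had a log2 change of 0.82 at 24 h and -1.58 at 48 h. Per gene, limma called 0 genes for the difference on the deposited values (64 at an unadjusted p under 0.05), and 4 on centred arrays, all lower, Mx1 (-3.29), Cxcl10 (-2.59), Ifit3 (-2.38) and Oas1a (-1.66). Adjusted over the list alone, 9 of the 26 interferon-stimulated genes were lower. Mitosis and S phase genes were also less high at 48 h (median differences -0.29 and -0.30, both with adjusted p = 0.710 with an estimated correlation), with 0 members past either test. camera called 12 of 33 lists for the difference, 2 upward and 10 downward, 0 with an estimated correlation and 1 with an estimated correlation on centred arrays.

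**Figure D4:**
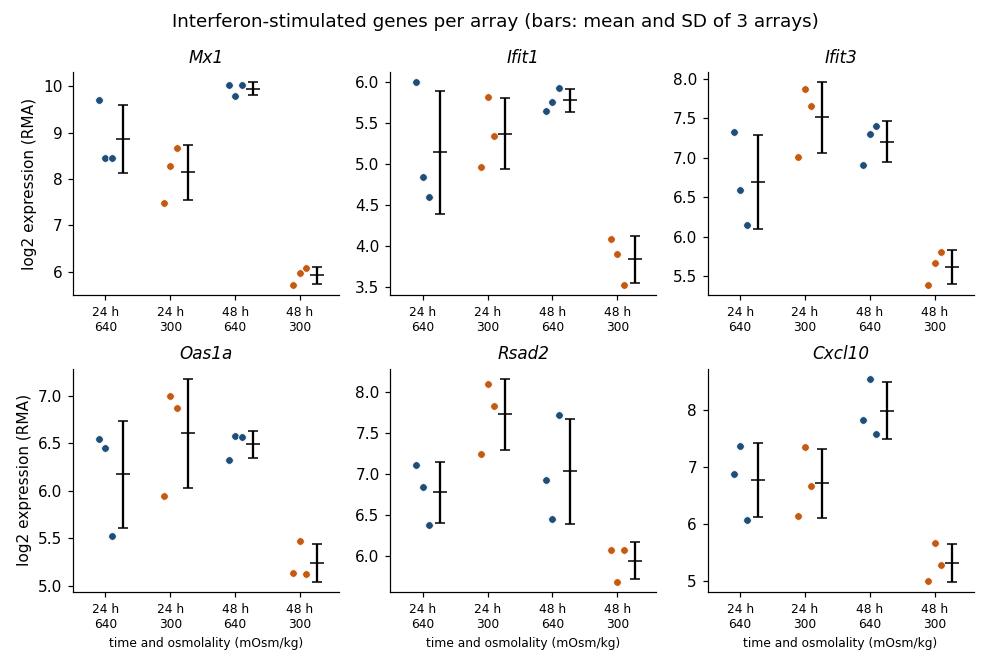
Log2 expression (RMA, vertical axis) of 6 interferon-stimulated genes on each of the 12 arrays, by time and osmolality, with blue points at 640 and orange points at 300 mOsm/kg and black bars for the mean and SD of 3 arrays. Mx1 had means of 8.87 and 8.14 at 24 h, at 640 and 300, and of 9.95 and 5.92 at 48 h.

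The last comparisons followed time in culture within each osmolality. The scale of the arrays fell between the times, with a median log2 change of all genes of -0.41 at 640 and -0.38 at 300, so changes are given relative to the array medians. On centred arrays at 640, the 5 largest rises from 24 h to 48 h were those of the secreted protein Cthrc1 (1.72), A2m, the protease inhibitor alpha-macroglobulin (1.65), the matrix protein Mgp (1.64), Cxcl10 (1.63) and the adaptor Sla (1.62). At 300, Il1rl1, an interleukin receptor (2.00), Capn6 (1.98), Serpinf1 (1.76), Serpine2 (1.57) and the smooth muscle protein Cnn1 (1.53) rose most. Mx1 (-1.79), the prostaglandin reductase Ptgr1 (-1.51), Ifit3 (-1.46), the interferon-induced Rsad2 (-1.35) and the quinone reductase Nqo1 (-1.30) fell most.

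On centred arrays 20 genes rose and 0 fell at 640, and 24 rose and 13 fell at 300, the genes named being chosen on these values. On the deposited values limma called 0 genes for either comparison (4077 and 3369 genes at an unadjusted p under 0.05). Without replicate 3 at 640 and 24 h the count at 640 was 3891, with 3878 falls. Without replicate 1 at 300 and 24 h the count at 300 was 3390, with 3381 falls. The arrays left out are the 2 at 24 h with medians like those at 48 h, so these falls carry the shift of scale between the times. Relative to the array medians, the 13 fibroblast markers had a median of 0.95 at 640 and 0.91 at 300, and the 14 macrophage and leukocyte markers 0.62 and 0.63. With an estimated correlation on centred arrays the fibroblast markers had adjusted p = 0.0170 and 0.0182 and the macrophage markers 0.0170 and 0.0244, in the order 640 and 300. On the deposited values the fibroblast markers had adjusted p = 0.0562 and 0.0595 with an estimated correlation, and the macrophage markers 0.125 and 0.172. Mitosis genes had -0.38 at 640 and -0.73 at 300, with adjusted p = 0.0688 and 0.0169 with an estimated correlation on centred arrays and 0.641 and 0.172 on the deposited values. Interferon-stimulated genes had 0.43 at 640 and -0.13 at 300, with adjusted p = 0.0311 and 0.119 with an estimated correlation on centred arrays and 0.211 and 0.931 on the deposited values. On the deposited values camera called 14 of 33 lists at 640 and 9 at 300, 0 and 0 with an estimated correlation, and fry 0 and 2, the 2 being mitosis and S phase. On centred arrays 3 and 5 lists were called with an estimated correlation, fibroblast and macrophage markers at both, with interferon-stimulated genes at 640 and mitosis, S phase (adjusted p = 0.0169) and actin genes (adjusted p = 0.0278) at 300. Time of culture and any difference in array processing between the times cannot be told apart here.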

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

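All tests of explanations in this part were chosen after the results they bear on had been seen. The mean array medians differed between osmolalities by 0.0134 at 24 h and -0.00187 at 48 h (300 minus 640). A shift of whole arrays could thus move a list by little, and a rescaling of them could hardly have come out otherwise. Intervals over members treat the genes of a list as independent and do not measure the spread between samples.

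At 300 relative to 640, 12 lists differed between 24 h and 48 h by a test of the difference itself, each with the median difference of its genes on the log2 scale. Lower at 48 h were interferon-stimulated genes (-0.36), mitosis (-0.29), S phase (-0.30), principal cell genes (-0.16), Nrf2 targets (-0.19), cell volume and ion transport (-0.0993), prostaglandin genes (-0.0947), osmolyte genes (-0.17), fatty acid and triglyceride synthesis (-0.0689, adjusted p = 0.0563 on centred arrays, which ended its call) and hypoxia (-0.0677). Higher were actin and SRF or YAP targets (0.0878) and urothelium markers (0.19). With an estimated correlation none was called, the lowest being the interferon-stimulated genes (adjusted p = 0.0773). On centred arrays 4 genes differed between the times, Mx1 (-3.29), Cxcl10 (-2.59), Ifit3 (-2.38) and Oas1a (-1.66). Groups of 3 were not searched for single samples far from the others.

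The interferon-stimulated genes moved from a median of 0.23 at 24 h to -0.19 at 48 h. An array-wide scale can hardly account for it, given the balance of the array medians. The median difference was -0.37 after cyclic loess (95% interval over members -1.27 to -0.21). As the whole cause, 1 array fits it poorly, since the median nearest to 0 with 1 array left out was -0.26 (without replicate 3 at 300 and 24 h). Single arrays did move its size, to -0.58 without replicate 1 at 300 and -0.55 without replicate 1 at 640, both at 24 h. Macrophage and leukocyte markers had a median difference of -0.0212 with a 95% interval of -0.19 to 0.10 over members, which leaves a change in the share of leukocytes open. What caused the difference between the times was not tested.

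Principal cell genes were lower at 300 at 48 h, with a median of -0.39 and Aqp2 at -4.41. After cyclic loess the median was -0.40, which the balance of the array medians between osmolalities makes likely in any case. With 1 array left out the median ran from -0.53 to -0.28. As the whole cause, 1 array fits this poorly, since the median stayed below 0 whichever array was left out. The 95% interval over members reached 0.0507 without replicate 1 at 300 and 0.0350 without replicate 2 at 640, both at 48 h. The medians there were -0.46 and -0.36, and such intervals do not measure the spread between samples. A lower share of epithelium would lower junction and keratin genes with them, and that list had a median of 0.0183 (95% interval -0.08 to 0.22 over members). Fewer principal cells among other epithelial cells was not tested, and the cause stays open.

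Mitosis genes were higher at 300 at 24 h, all 24 of them, with a median of 0.75. The median was 0.77 after cyclic loess, 0.63 to 1.06 with 1 array left out, and 0.87 without the pair of arrays with low medians, so neither 1 array nor this pair explains it alone. An array-wide scale could hardly do so either, given the balance of the array medians. Cell division itself was not measured, and the cause stays open.

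Other splits of the arrays show how far chance can be excluded. The 6 arrays of 1 time make 10 splits, too few for a share under 0.05. At 24 h 3 of 10 splits gave at least the real 13 genes, with 2162 as the highest other, and 3 of 10 did so for changes of at least 2-fold (13 against 665). The largest put replicate 1 at 300 with replicates 1 and 3 at 640, and with centred arrays it still called 878 against the real 95, which points to a structure of the arrays at 24 h other than osmolality. At 48 h the real split alone reached its count, 1 of 10, with 104 against 0 genes, and 101 against 0 by at least 2-fold. Lists called were 13 against 7 at 24 h and 18 against 13 at 48 h, again 1 of 10 each. For time at 640 and at 300, the real count was 0 genes, which every one of the 10 splits reaches by definition (10 of 10, highest other 0), so these splits say nothing. Of 100 splits for the average over both times, 5, the real one among them, gave at least the real 185, with 806 as the highest. On centred arrays 3 of 100, again with the real one, gave at least 497, a share under 0.05, although the highest other was 2185. Splits that keep the real groups at 1 of the 2 times were not left out, and such splits carry any effect of osmolality at that time. These shares therefore do not measure chance alone, and chance is not excluded for the average. For the difference between times, the real count of 0 genes is likewise reached by definition (100 of 100, highest other 5499) and says nothing about chance. For the lists of that difference, 7 of 100 splits reached the 12, with 17 as the highest. These splits exchanged arrays of 24 h and 48 h within each osmolality, so uneven ones also carry the shift of scale between the times. The share therefore does not measure chance for the difference, and chance is not excluded. All these splits treat the arrays as exchangeable, while the deviations of arrays from their group means correlate in sets across osmolalities (0.576 to 0.844 within a time), which neither the splits nor the tests take into account. Splits that call several times the real count also point to such a structure. Shares of splits and genes that did not pass are to be read with that limit.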

How the results depend on the processing

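The pair of arrays with low medians at 24 h and the estimated correlation on centred arrays were chosen after seeing the data. Counts of called genes are given in one order: 24 h, 48 h, 24 h at least 2-fold, 48 h at least 2-fold, average, difference, time at 640 and time at 300, with 13, 104, 13, 101, 185, 0, 0 and 0 on the deposited values. They were 98, 304, 58, 156, 571, 2, 22 and 43 after cyclic loess, 95, 269, 56, 153, 497, 4, 20 and 37 with arrays centred, 139, 415, 87, 169, 680, 4, 9237 and 10190 with array weights and 20, 250, 20, 155, 357, 1, 8104 and 7306 without the pair of arrays with low medians. Of the genes counted for time at 640 and at 300, 9195 and 10117 fell with array weights, and 8079 and 7276 fell without the pair. The median log2 change of all genes over time was -0.41 at 640 and -0.38 at 300 on the deposited values. These falls thus carry the shift of scale between the times and do not count genes that changed relative to the others. The cause of the other changes in the counts was not tested. With only the groups compared, the counts were 3 and 217 at 24 h and 48 h, 3 and 145 by at least 2-fold, and 8 for time at 300. Trend and robust settings gave 1 for the difference and 5 for time at 300, and every probe set gave 3 for time at 640 and 3 at 300. With 1 array left out, which leaves fewer arrays, the counts ran from 4 to 24, 51 to 145, 4 to 24, 51 to 136, 108 to 260, 0 to 3, 0 to 3891 and 0 to 3390. The correlation of the changes at 24 h and 48 h across genes ran from 0.554 to 0.702, lowest without replicate 2 at 640 and 24 h.

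Lists called at 24 h, at 48 h and for the difference were 13, 18 and 12 with the preset correlation, 0, 0 and 0 with an estimated one, 0, 0 and 0 by fry, and 5, 7 and 1 with an estimated correlation on centred arrays, all among those first called. The mixed test of fry, for changes of either sign, called 3, 7 and 1. With 1 array left out they ran from 10 to 15, 16 to 20 and 7 to 13, the difference lowest without replicate 3 at 640 and 48 h.

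Arrays with the same replicate number deviated together only for replicate 2 (correlations of deviations from group means between 640 and 300 of -0.13, 0.84 and -0.21 at 24 h and -0.23, 0.80 and -0.22 at 48 h, for replicates 1, 2 and 3). By this check the numbers do not pair the samples. The replicate block gave 15 and 87 genes at 24 h and 48 h, 15 and 87 by at least 2-fold, 170 for the average, 0 for the difference, 0 for time at 640 and 4 for time at 300.

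Of 60 calls of named genes at 24 h and 48 h, 60 were kept after cyclic loess, centring, array weights, the mean of probe sets and the low pair left out, while 59 were kept without dim genes, 58 with trend and robust settings, 53 with every probe set, 51 with the replicate block, 50 with only the groups compared and between 43 and 60 with 1 array left out. None reversed. Values that did not pass and changed sign in some fits with 1 array left out ran from -0.0486 to 0.655 for Ifit1 at 24 h, -0.407 to 0.236 for Cxcl10 at 24 h, -0.158 to 0.0858 for Rhbg at 24 h and -0.186 to 0.0986 for Isg15 at 48 h, which was -0.03 on all arrays. Ifit1 at 24 h was -0.191 with array weights. Their cause was not tested. Signal over background is unknown, which limits statements on dim genes.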

Other observations

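Several gene groups of metabolism and stress had medians near 0 and were not called at either time, given as median log2 change and camera adjusted p at 24 h and at 48 h. With limma camera these were endoplasmic reticulum chaperones (0.0697, adjusted p = 0.0874, and 0.0435, adjusted p = 0.413), the tricarboxylic acid cycle (-0.0344, adjusted p = 0.798, and 0.0250, adjusted p = 0.628), fatty acid oxidation (-0.00974, adjusted p = 0.607, and 0.0743, adjusted p = 0.191), the pentose phosphate pathway (-0.0183, adjusted p = 0.968, and 0.0502, adjusted p = 0.628), amino acid transporters (0.0318, adjusted p = 0.636, and -0.0640, adjusted p = 0.413), immediate early genes (-0.0376, adjusted p = 0.559, and -0.0330, adjusted p = 0.104) and inflammatory mediators (-0.0238, adjusted p = 0.860, and -0.0397, adjusted p = 0.384), among which Cxcl10 fell at 48 h.

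The resemblance of arrays across osmolalities followed a crossed order of the replicate numbers at both times. The deviations from group means of replicate 1 at 640 and replicate 3 at 300 correlated with 0.576 at 24 h and 0.631 at 48 h, those of replicate 2 and replicate 2 with 0.844 and 0.795, and those of replicate 3 at 640 and replicate 1 at 300 with 0.825 and 0.780. Across the times, the deviations of the arrays of the second set correlated with 0.426 to 0.455, those of the third with 0.307 to 0.459 and those of the first with -0.01 to 0.12. The labels name no shared preparation, and no model with such sets was fitted. The 2 arrays at 24 h with low medians, replicate 1 at 300 and replicate 3 at 640, form the third set, and each correlated best with the 48 h array of its own osmolality and number (0.995 and 0.994). Whether the time labels of these 2 arrays are right is not settled here, and a wrong one would change the values at 24 h and over time.

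A test chosen after these values were seen took the 100 genes that differ most with time at the other osmolality, chosen on centred arrays without either of these 2. Replicate 1 at 300 was nearer to the 24 h mean of its own osmolality for 38 of 100 genes and replicate 3 at 640 for 42 of 100. The other 24 h arrays had 80 to 91 and the 48 h arrays 3 to 15. On a scale from 0 at the 24 h mean to 1 at the 48 h mean the 2 arrays lay at 0.632 and 0.607. This is outside both the other 24 h arrays (-0.0567 to 0.240) and the 48 h arrays (0.873 to 1.10). The 100 genes were chosen between 24 h arrays with high medians and 48 h arrays with low ones. They may therefore follow the scale, which the 2 arrays share with 48 h, as well as time. The test thus cannot decide on the time label, and a wrong one stays open. Some single genes lay on the side of 24 h and some on that of 48 h, all chosen after the values were seen or with the 2 arrays counted as 24 h. Those of the first kind come first. On replicate 1 at 300, A2m was 6.08 (7.07 to 7.78 at 48 h), Serpinf1 6.85 (8.23 to 8.83), Mx1 7.49 (5.71 to 6.09) and Top2a 9.04 (7.98 to 8.11). On replicate 3 at 640, Mgp was 6.69 (8.10 to 8.25 at 48 h), Cthrc1 5.75 (6.95 to 7.69), Serpinf1 7.34 (8.20 to 8.57) and Mx1 8.45 (9.78 to 10.04). On the side of 48 h lay Slc14a2 at 7.44 (7.31 to 7.63 at 48 h) and Slc4a11 at 7.65 (7.02 to 7.39) on replicate 1 at 300. So did Hmgn2 at 9.65 (9.11 to 9.31 at 48 h) on replicate 3 at 640.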
